A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

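The experiment compared the abundance of molecular barcodes (tags) that identify yeast deletion strains. Per the labels, a pool of 5896 Saccharomyces cerevisiae diploids, each lacking 1 copy of a different gene, was transformed with a cassette that replaces TUB1 by URA3 or, as the control, with a cassette that restores URA3 at its own locus. Transformants were selected for 2 days at 30 °C on synthetic medium without uracil, genomic DNA was prepared from each pool, and the upstream and downstream tags were amplified by PCR with common primers. Tags of the control pool were labelled with Cy5 and tags of the tub1 pool with Cy3, and both were hybridised together to a Hopkins tag array. Images were taken on a GenePix scanner and analysed with GenePix 5.1, per the labels. The labels give total RNA as the molecule, although the description names tags amplified from genomic DNA. The 2 arrays are experiments 1 and 2. The labels do not say whether these were separate transformations, so limma's p-values for single strains measure only the spread between these arrays, which may be technical. Camera at a preset correlation compares the strains of a list with other strains. Permutation and Fisher's exact p-values likewise compare strains. These do not measure the spread between experiments, and strains are not independent replicates. Both arrays had the same dye orientation, so a dye effect does not cancel.

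The deposited values are log2 ratios per spot, as the values themselves show: 100% of 40008 values were the log2 of a ratio written with 2 decimals, within 0.001 of a hundredth. The smallest linear ratio was 0.01. A linear ratio of 1e+06, found in 2 values, was taken as a filled-in number and treated as missing. The deposited medians were -0.12 on array 1 and -0.04 on array 2. The background correction and normalization applied by the authors are not given in the sources used here, and spot intensities were not used here, so weak spots could not be removed by brightness.

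The direction of the deposited ratio is not stated in the labels. The planned check was the TUB1 deletion strain itself, whose tags should be lost from the tub1 pool, but 0 of its 4 tag measurements held a value, the only 1 of 5325 gene symbols for which this was so, and URA3 had 0 probes. The plan was written for the tub1 pool over the control pool. Since the check gave no value, the deposited sign was kept, and ratios are called positive or negative, not lower or higher in a pool. From the dyes in the labels and the scanner program's usual ratio of red over green, a positive ratio is likely the control pool over the tub1 pool, so that a strain with a positive ratio would have fewer tags in the tub1 pool. The opposite reading is not excluded.

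Probes were named through the platform's gene annotation, and symbols and gene order came from the NCBI gene table of assembly R64, used for names and neighbours only because no build is named for the array. Of 22575 probes, 18794 had 1 gene symbol, 0 had several and 3781 had none, and 18786 of the named probes were matched to the gene table. The probes formed 2 tag sets, since each named probe and the probe 10971 numbers later carried the same gene in 100% of cases. Which set holds the upstream tags is not stated, so they are called the first and second tag set. In 781 strains each tag had 6 spots and in the others 1. Symbols with more than 1 probe in a tag set (105) were left out because their tags could not be assigned to 1 strain.

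Spots of a tag were averaged, each array and tag set was centred on its median, and both tags of a strain were averaged to 1 value per array. Centring moved array 1 by 0.12 and array 2 by 0.04 upward against the values given above. The 5219 strains with a value on both arrays were tested against a ratio of 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept and eBayes, two-sided, Benjamini-Hochberg adjustment over all strains, threshold 0.05). An untested count of strains at least 2-fold from 0 on both arrays was also made, with the number expected if the arrays were unrelated. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, and adjusted over the 18 lists with at least 3 measured members. Camera compares the strains of a list with all other strains, so its direction is relative to these and not to 0. With an estimated correlation, used as an alternative, it has 1 residual degree of freedom. Hardly any list could then pass, so those p-values decide nothing. The 2 further lists had fewer members and were given as values. Agreement between arrays was Pearson's r and Spearman's rho across strains, with intervals from 1000 bootstrap resamples of strains. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.

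The limma step was tested on simulated ratios for 5219 strains. With a spread of 0.05 log2 on each array it called 50 of 50 strains at each of the true log2 ratios 1, 2, 4 and -1. With the difference between the real arrays as the noise it called 0 of 50 at each of these sizes. In both runs the noise entered the arrays with opposite signs, so each simulated mean equalled its true ratio. A true ratio of 0 was given to 5019 of the 5219 strains. The adjustment depends on how many strains differ, so the result holds for this setting and does not show that calls were out of reach in the real data. A sign-flip test of 2 arrays cannot give a two-sided p under 0.5. The number of arrays limits the precision of every value.

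The strains, lists, tests and first set of alternatives were chosen before the data were examined. Named strains were TUB1, TUB2, TUB3 and URA3 where measured; the 12 most positive and 6 most negative strains; and, in each tested list, members past the threshold or else the single most extreme member on the positive side. Because no strain passed the threshold, the 12 and 6 were filled, as the rule provides, by the smaller of both arrays' absolute log2 ratios among strains with 1 sign on both arrays. For the lists the rule takes the lowest ratio of the tub1 pool over the control pool, which is the positive end under the likely direction. Strains named outside this rule are said to have been chosen after their values were seen. Alternatives left out centring, used quantile normalization, each tag set alone, only strains measured by both tags, tags kept apart with a random block, other eBayes settings and thresholds, an estimated inter-gene correlation, and each array alone. Further alternatives were chosen after seeing the data: leaving out the second tag set of chromosome I, keeping only strains with 6 spots per tag and a spot SD under 0.3 for every tag on both arrays, and the tag set as the random block. The RSC, TFIID and COPII lists were also chosen after seeing the data. In the closing section 3 tests replaced earlier forms after their values were seen, with bounds set when the new values were known: the share of low tags also low on array 2 (19.0%, read at first as excluding a shared difference), the spot scatter of low tags (10.9 times, read at first as fitting little signal) and that of chromosome I tags (10.5 times, read at first as fitting a missing tag). The earlier forms had no baseline or did not match tags on their ratio, and the new forms left all 3 explanations open.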

Results

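Tag ratios of 5219 heterozygous deletion strains were compared between a pool transformed with a TUB1 deletion cassette and a control pool transformed with a URA3 cassette, on 2 arrays in 1 group. TUB1 encodes the major alpha-tubulin, and TUB3 encodes a second, minor alpha-tubulin. The series addresses synthetic haploinsufficiency, that is, which genes in a single copy alter the growth of diploids that also lack 1 copy of TUB1. Ratios are given as log2 with the deposited sign, centred on the median, as mean ± SD over n = 2 arrays. A positive ratio likely means fewer tags in the tub1 pool. This reading rests on the dye labels and the usual ratio of the scanner program, because the TUB1 deletion strain gave 0 of 4 tag values and could not serve as the check.

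The strain lacking 1 copy of TUB3 had the most positive ratio of all 5219 strains. Its log2 ratio was 4.22 ± 0.32, or 18.7-fold, and its 4 tag measurements were 4.25 and 3.74 on array 1 and 4.57 and 4.33 on array 2. TUB2, the beta-tubulin gene, stood at 0.00 ± 0.15. Ranked by the smaller of both arrays' ratios, TUB3 was followed by DIA4 (2.06 ± 0.40), a mitochondrial seryl-tRNA synthetase gene, and RSC9 (1.83 ± 0.31), a subunit of the RSC chromatin remodelling complex. CIN4, which encodes a GTPase of the tubulin folding pathway, had a ratio of 1.53 ± 0.04, with tag values from 1.30 to 1.70. MCD1, the kleisin subunit of cohesin, had 1.47 ± 0.04, and RSC8, a second RSC subunit, had 1.44 ± 0.15.

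The other strains of the positive end were PRO1, ERG12, APE3, MSS4, YDL144C and BLI1. PRO1, which acts in proline synthesis, averaged 2.01 ± 0.74, but its second tag gave 2.54 and 3.38 while its first tag gave -0.41 on array 2 and no value on array 1. ERG12, the mevalonate kinase gene, had 1.48 ± 0.01 and APE3, a vacuolar aminopeptidase gene, had 1.63 ± 0.26. MSS4, a phosphatidylinositol 4-phosphate kinase gene, had 1.34 ± 0.03. YDL144C had 1.37 ± 0.07 and BLI1 had 1.38 ± 0.18.

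At the negative end, SLI15, a chromosomal passenger protein that binds microtubules, had a log2 ratio of -3.80 ± 0.90, with tag values of -3.72 and -2.62 on array 1 and -6.60 and -2.28 on array 2. RAD4, a nucleotide excision repair gene, had -3.77 ± 0.24, and RCO1, a subunit of the Rpd3S deacetylase complex, had -3.67 ± 0.27. YML083C, which lies beside TUB1, had -3.37 ± 0.39, and SLA1, which acts in actin assembly and endocytosis, had -2.82 ± 0.13. CMD1, the calmodulin gene, averaged -3.27 ± 0.10. For CMD1 this rested on the second tag, at -6.52 and -6.60, while the first tag stood at -0.15 and 0.21. The RAD4 tags also differed, with -1.35 and -0.60 for the first and -6.52 and -6.60 for the second. On array 2 the tags of SLA1 were -0.40 and -5.04 and those of YML083C were -1.17 and -5.01, a spread that the SD between arrays does not show. Values of -6.52 on array 1 and -6.60 on array 2, found in SLI15, CMD1 and RAD4, lie at the smallest ratio in the data, so the means of these strains and their order are uncertain.

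None of these strains passed the test. With limma, 0 strains with positive and 0 with negative ratios had an adjusted p under 0.05, and the smallest adjusted p was 0.229, which TUB3 shared with the other strains of both ends. At an unadjusted p under 0.05 there were 476 positive and 612 negative strains, against 261 expected by chance in both directions together. Without moderation, and with robust eBayes, the counts were again 0 and 0. Keeping both tags of each array in the fit with the array as a random block gave 360 positive and 170 negative calls, TUB3 among them at an adjusted p of 0.00756. With the tag set as the block, a choice made after seeing the data, limma called 1 positive strain, TUB3 (adjusted p 0.0236), and 2 negative strains. Among the 553 strains with 6 quiet spots per tag, a restriction also made after seeing the data, it called 49 positive and 14 negative strains. That restriction kept 9 of 87 strains with 6 spots per tag and a mean at or under -1, against 14 of 18 at or over 1. It therefore removed most strongly negative strains. Between these bounds it kept 530 of 674, and calls in both directions lay there too. What set the balance of both counts was not tested.

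**Figure D1:**
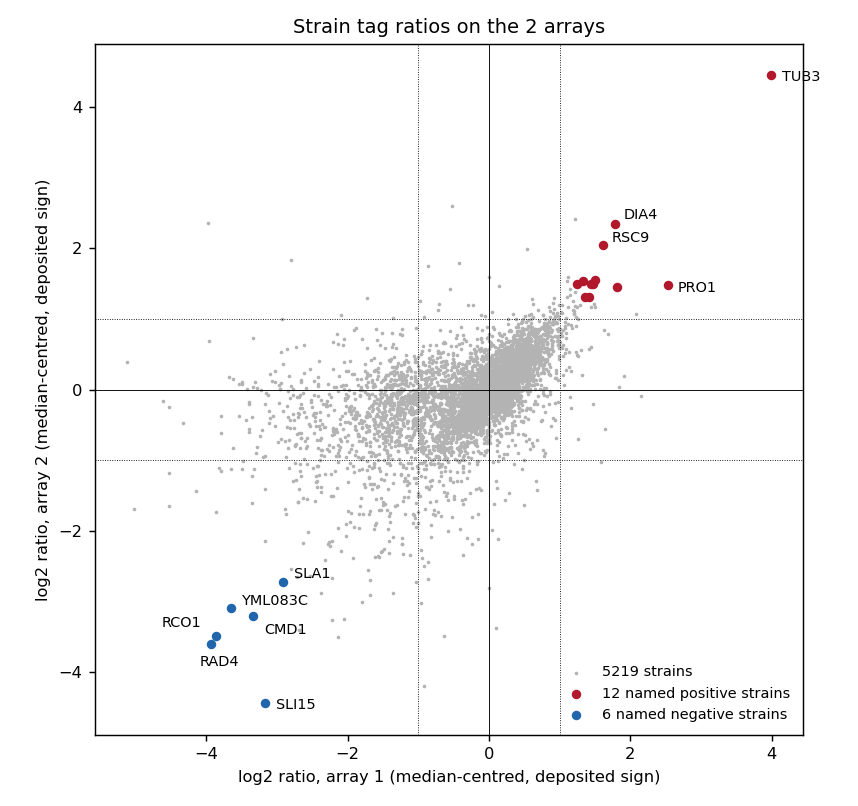
Median-centred log2 tag ratio of each of 5219 strains on array 1 (horizontal) and array 2 (vertical); dotted lines mark 2-fold, red points the 12 named positive strains and blue points the 6 named negative strains. TUB3 stands apart at 3.99 and 4.45, and many strains reach low ratios on array 1 while they stay near 0 on array 2.

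The strains at both ends were shared by the arrays more often than expected from unrelated arrays, a comparison made without a test. Both arrays had the same tags and dye orientation, so a bias of a tag or dye would be shared too. An excess over unrelated arrays therefore does not by itself show a difference in strain abundance. At least 2-fold positive ratios on both arrays were found for 38 strains, where 1.34 would be expected if the arrays were unrelated, and 2-fold negative ratios for 195, where 58.8 would be expected. On array 1 alone 82 strains were 2-fold positive and 1006 were 2-fold negative, and on array 2 alone the counts were 85 and 305. For 21 strains both tags were at least 2-fold positive on both arrays, and for 31 strains both were at least 2-fold negative. Those 21 included TUB3, DIA4, RSC9, CIN4, ERG12, APE3, MCD1, RSC8, MSS4 and BLI1. Those 31 included SLI15, RCO1 and YML083C.

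Across strains, which are not independent replicates, the arrays correlated with Pearson's r of 0.526 (95% bootstrap interval 0.498 to 0.554) and Spearman's rho of 0.606 (0.585 to 0.627). The sign was shared by 74.4% of strains. The same tag correlated across arrays with a rho of 0.616 in the first set and 0.647 in the second. Different tags of the same strain correlated less, with a rho of 0.264 on array 1 and 0.377 on array 2.

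Strains lacking 1 copy of a tubulin folding cofactor had mostly positive ratios. Of 6 measured, 4 were positive and 2 negative on both arrays, and the median was 0.67. Besides CIN4, the ratio was 0.87 ± 0.16 for CIN2 and 0.48 ± 0.07 for CIN1, whose products act in the same pathway. RBL2, which encodes a beta-tubulin binding protein, had 1.82 ± 0.85, but its tags disagreed, at -0.62 and 3.06 on array 1. ALF1 had -0.43 ± 0.17 and PAC2, a cofactor for alpha-tubulin, had -2.05 ± 0.91. By limma 0 members passed over all strains. Adjusted over the list alone 4 passed: CIN4, CIN2, RBL2, whose tags disagreed, and PAC2, which was negative. The list did not pass with camera (adjusted p = 0.230). With an estimated correlation, a setting in which hardly any list could pass, camera's adjusted p was 0.928.

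Strains of the spindle assembly checkpoint, which delays anaphase until chromosomes are attached, were positive on both arrays in 5 of 6 cases. The median was 0.48. MPS1 had 0.66 ± 0.10, MAD1 had 0.55 ± 0.16, MAD3 had 0.51 ± 0.39 and MAD2 had 0.45 ± 0.11, while BUB3 stood at 0.05 ± 0.20. The MAD3 tags disagreed on array 1, at -0.24 and 1.81. No member passed with limma over all strains or adjusted over the list alone, and 2 had an unadjusted p under 0.05. Camera gave an adjusted p of 0.0579, which missed the threshold; it was 0.0337 with uncentred ratios and 0.0471 after quantile normalization. With an estimated correlation camera's adjusted p was 0.928, but in that setting hardly any list could pass, so it decides nothing.

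The other microtubule and chromosome segregation lists with at least 3 measured members had strains on both sides of 0. Because the direction is only likely, the lowest member is given beside the highest, and these lowest members were chosen after their values were seen. Kinetochore proteins outside the DASH complex had a median of -0.02, with 11 of 27 positive and 11 of 27 negative on both arrays; CHL4 was highest at 0.92 ± 0.04 and MTW1 lowest at -1.85 ± 0.49. The MTW1 value rested on its second tag, at -4.20 and -2.60 against -0.20 and -0.41 for the first, and the second tags of chromosome I strains such as this were generally low. In the DASH complex, which couples kinetochores to microtubules, the median was 0.13 (0.08 on array 1 and 0.21 on array 2). DAD2 was highest at 0.53 ± 0.46 and DAD1 lowest at -0.92 ± 0.29, with the second tag of DAD1 at -1.94 and -1.69 and the first at -0.31 and 0.27. Motors and microtubule-associated proteins had a median of 0.00 (-0.02 and 0.19 on arrays 1 and 2), with STU2, a microtubule polymerase, highest at 0.82 ± 0.10 and SHE1 lowest at -1.46 ± 1.34. The dynein and dynactin pathway had a median of -0.21 (-0.23 on array 1 and 0.10 on array 2), and NUM1, which anchors dynein at the cortex, was highest at 1.03 ± 0.14. PAC11, a dynein intermediate chain gene, was lowest at -1.71 ± 1.11, with its first tag at -1.49 and -4.64 and its second at -0.36 and -0.35. Spindle pole body strains had a median of 0.07 (-0.11 and 0.20 on arrays 1 and 2), from SPC72 at 0.59 ± 0.17 to CMD1, the 1 member that passed adjusted over the list alone, with a mean that rested on its second tag. SPC72, like MTW1, is a chromosome I strain, and its mean rested mostly on its second tag, at 1.03 and 1.06 against -0.10 and 0.35 for the first. Cohesin strains had a median of -0.14 (-0.17 on array 1 and -0.06 on array 2), and MCD1, the highest, was the 1 member that passed adjusted over the list alone. SMC1, another cohesin subunit gene, was lowest at -1.57 ± 0.78. The anaphase-promoting complex had a median of -0.42 (-0.62 on array 1 and -0.06 on array 2), with 9 of 15 members negative on both arrays, CDC27 highest at 0.26 ± 0.02 and APC2 lowest at -1.16 ± 0.46. Camera's adjusted p was 0.832 for kinetochore proteins, 0.688 for DASH and for motors, 0.901 for dynein, 0.886 for the spindle pole body, 0.988 for cohesin and 0.230 for the anaphase-promoting complex. In the chromosomal passenger complex 2 members were measured, SLI15 and IPL1 (-0.75 ± 0.25). Both were negative on both arrays, with a median of -2.28, and by limma 0 passed over all strains and 2 passed adjusted over the list alone. Camera was not run on so short a list.

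Chaperones of tubulin folding showed no shared direction. The prefoldin complex, which delivers unfolded tubulin and actin, had a median of -0.03 (0.12 on array 1 and 0.10 on array 2) and a camera adjusted p of 0.688; YKE2 was highest at 0.62 ± 0.01 and GIM3 lowest at -0.71 ± 0.78. The CCT chaperonin had a median of 0.05 (-0.09 on array 1 and -0.03 on array 2) and an adjusted p of 0.900, with CCT4 highest at 0.30 ± 0.02. CCT7 (-1.42 ± 1.33) and CCT8 (-1.35 ± 1.47) differed widely between arrays. For CCT, motors and the spindle pole body the mean was negative (-0.28, -0.14 and -0.34) although the median was not. Camera placed these lists above the other strains. Mean and median were both negative for prefoldin (mean -0.08), other kinetochore proteins (mean -0.14) and SWR1 (mean -0.10). Camera placed these lists above the other strains too, which says nothing about the sign of their ratios. Without centring the medians of CCT, motors and the spindle pole body turned negative, and after quantile normalization that of other kinetochore proteins turned positive.

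None of the comparison lists outside the microtubule system passed camera. Proteasome strains had a median of -0.31, with 20 of 30 negative on both arrays (camera adjusted p 0.188), and PRE3 was highest at 0.49 ± 0.16 and PRE10 lowest at -1.66 ± 1.33. Actin and Arp2/3 strains had a median of -0.28 (adjusted p 0.449), and ARC18 was highest at 0.43 ± 0.06 and ACT1 lowest at -1.48 ± 1.56. Cytosolic ribosomal protein strains had a median of -0.24 (-0.23 on array 1 and -0.11 on array 2), with 54 of 115 negative and 29 positive on both arrays (adjusted p 0.419); RPL26B was highest at 1.07 ± 0.22 and RPL30 lowest at -2.80 (-3.86 on array 1 and -1.74 on array 2). The SWR1 complex had a median of -0.09, with opposite signs on array 1 (-0.49) and array 2 (0.31), an adjusted p of 0.688, values from 0.70 ± 0.51 for SWR1 itself to -1.80 ± 1.16 for VPS72. Uracil synthesis strains, a control for the selective medium, had a median of -0.28 (-0.49 on array 1 and -0.06 on array 2; adjusted p 0.760), and URA5 was highest at 0.19 ± 0.15 and URA4 lowest at -0.69 ± 0.80. In these lists and in those above, estimated correlations gave camera adjusted p-values of 0.928 or more. With 1 residual degree of freedom per strain such estimates are coarse and hardly any list could pass, so these values decide nothing.

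**Figure D2:**
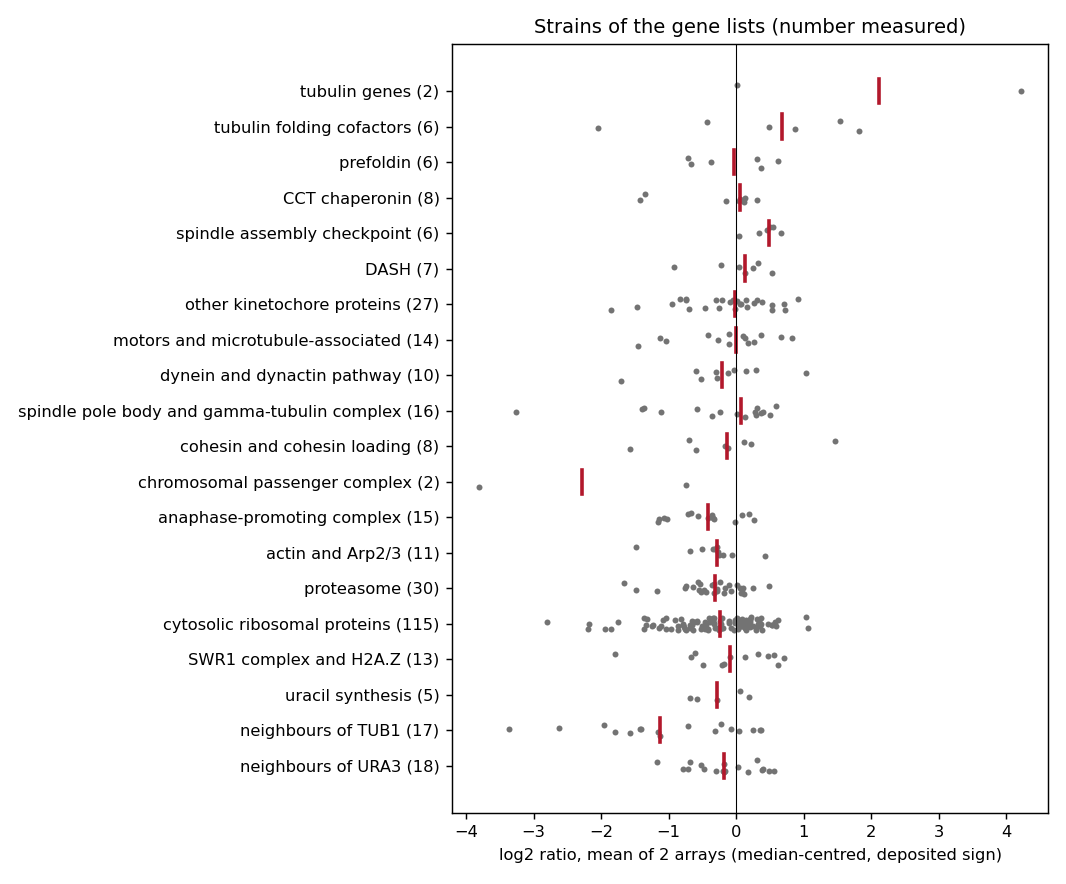
Mean log2 tag ratio over both arrays (horizontal) of each measured member (grey points) of the 20 gene lists, with the number measured in brackets and the median as a red bar. Checkpoint strains lie between 0.05 and 0.66, and neighbours of TUB1 have a median of -1.13.

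Strains lacking genes next to TUB1 had mostly negative ratios. Of 17 measured neighbours of TUB1, 12 were negative on both arrays and 4 positive, and the median was -1.13 (-1.57 on array 1 and -0.52 on array 2). YML083C had the lowest ratio, followed by TDA9 (-2.63 ± 0.35) and YML082W (-1.96 ± 0.55), while GIM5, a prefoldin gene at the edge of the region, was highest at 0.37 ± 0.07. The 18 neighbours of URA3 had a median of -0.18 (-0.28 on array 1 and -0.02 on array 2), with 9 negative and 6 positive on both arrays, and UBC8 was highest at 0.55 ± 0.36 and NPP2 lowest at -1.18 ± 0.21. Camera's adjusted p was 0.134 for neighbours of TUB1 and 0.900 for neighbours of URA3; after quantile normalization the first reached 0.0471. With an estimated correlation, a setting in which hardly any list could pass, camera's adjusted p was 0.928 for either list. By limma 0 neighbours of TUB1 passed over all strains and 3 passed adjusted over the list alone. The difference between both lists was not tested.

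**Figure D3:**
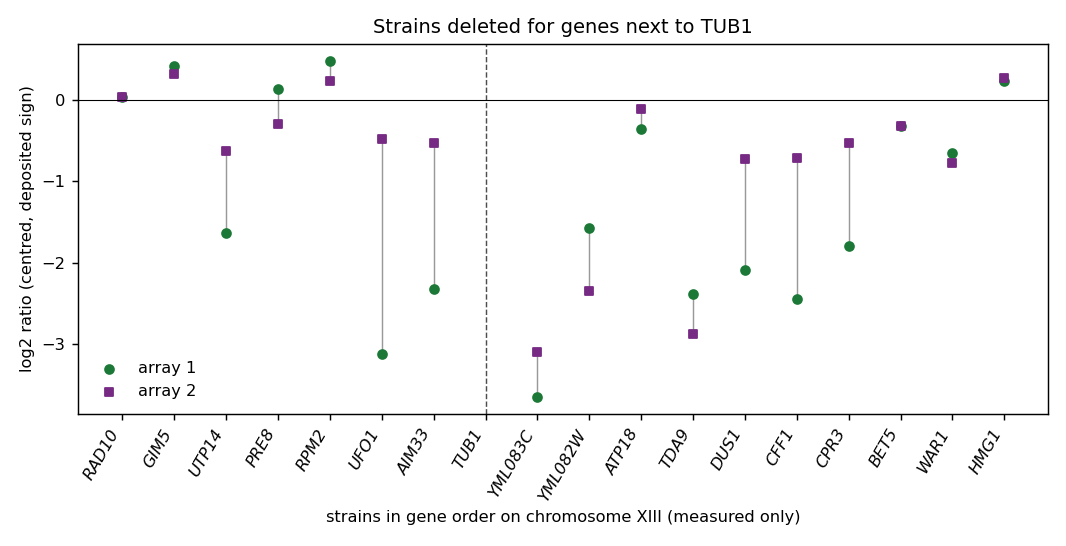
Centred log2 tag ratio on array 1 (circles) and array 2 (squares) of strains lacking genes next to TUB1, in gene order; the dashed line marks TUB1, which had no value. YML083C, YML082W and TDA9 are negative on both arrays, and the outermost strains, RAD10 and HMG1, lie near 0. WAR1 and UTP14, close to the edges, are also negative on both arrays, while ATP18, closer to TUB1, is only weakly negative.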

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

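The tests in this part were chosen after the results were seen, except the lists of neighbours of TUB1 and URA3.

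Some tags to which no gene is assigned here, and which enter no comparison above, had ratios far from 0. Of 582 unnamed tag pairs measured by both tags on both arrays, 4 were at least 2-fold from 0 with 1 sign in all 4 values. Among the 5191 named strains measured by both tags on both arrays, 21 were so on the positive and 31 on the negative side. Such values are thus not particular to unnamed pairs. Probes 3941 and 14912 averaged 2.27 ± 0.57, and probes 1883 and 12854 averaged 1.26 ± 0.03 (SD, n = 2 arrays). Probes 2230 and 13201 averaged -1.68 ± 0.12, and probes 2307 and 13278 averaged -3.15 ± 0.31. The median of all such pairs was -0.11, and no control tags were used here as a background.

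On array 1, 13.2% of tags in the first set and 15.9% in the second had ratios at or under -1.5, against 3.84% and 3.99% on array 2. Of the 232 such tags with 6 spots, 19.0% were at or under -1.5 on array 2 as well, against 0.662% of tags within 0.5 of 0, and 47.4% were among the 232 lowest there, against 14.9% expected from unrelated arrays, so that a difference between the pools shared by both experiments stays open for part of them; because the tags were picked on array 1, weaker values on array 2 exclude nothing. Their 6 spots scattered on array 1 with a median SD of 0.557, which was 10.9 times that of tags within 0.5 of 0. This alone does not show little signal, because scatter rose with the size of positive ratios too. From tags between 0.5 and 1 to the 14 tags at or over 1.5 it rose 2.92 times. Those 14 tags still scattered less (median SD 0.157) than the low tags. Tags over -1.5 to -0.5 also scattered more (0.118) than tags over 0.5 (0.0576). The groups were not matched on the size of the ratio, so size was not shown to account for the scatter of low tags. Little signal and a true difference of these tags between the pools cannot be told apart here, as spot intensities were not used. Strains such as HIP1 (-2.69 ± 0.05), chosen after its values were seen, were as low on both arrays for both tags.

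The second tag of chromosome I strains was low on array 1, with a median of -3.52 over 73 strains, and stood at -0.65 on array 2. The first tag of these strains was not low, with a median on array 1 of 0.0722. A tag absent from both pools could also give a ratio near 0. Where first tags had 6 spots, their median spot SD on array 1 was 0.0473, against 0.0587 on other chromosomes. On array 2 it was 0.232, against 0.205. The spots of these first tags thus scattered about as those of other strains did. How much an absent tag would scatter is not known here, so absence of these strains is not decided without spot intensities. A local fault of the array surface is argued against by 69 copies of these tags in 14 strains, placed at distant probe numbers, whose median on array 1 was -2.44. A tag that is missing or poorly amplified stays open, since spots of 5 of these tags scattered 1.20 times as much as those of 45 equally low tags of the set on other chromosomes, so that scatter went with the low ratio and decided nothing. No biological explanation was tested, and the mean of MTW1, for example, contains such a tag.

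Negative ratios next to TUB1 became weaker with distance. Over the 17 strains, Spearman's rho between the mean log2 ratio and the distance in gene order from TUB1 was 0.746 (Pearson's r 0.729; permutation p 0.00098, two-sided), with a rho of 0.676 on array 1 and 0.549 on array 2, where the first tag set alone gave 0.340 (permutation p 0.182) and the second 0.627 (permutation p 0.00784), against 0.153 (permutation p 0.541) for the 18 neighbours of URA3. The 6 strains within 4 open reading frames were negative on both arrays, with a median of -1.88, against -0.32 for the 11 farther ones. A stretch of low strains by chance is argued against by its rarity, since 65 of 4926 other, overlapping stretches of 17 strains (1.32%) had a median as low, 31 of them on chromosome I. The median tag of the list on array 1 was -1.10, within the broad range of the chromosome I second tag set but above its upper quartile. On array 2 it was -0.51, within the quartiles of that set. Those tags were not shown to have weak signal, so the comparison decides nothing about it. Weak signal remains open alongside a hypothesis of nearness to the cassette site, for which no mechanism was tested.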

How the results depend on the processing

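Alternatives chosen after seeing the data were the strains with 6 quiet spots per tag, the omission of the second tag set of chromosome I, and the tag set as a random block; the others were planned. Limma's counts were also 0 positive and 0 negative without centring, after quantile normalization, with either tag set, with both tags required, without the second tag set of chromosome I, with robust or no moderation, at adjusted p under 0.01 or 0.1, with a minimum change of 1.5-fold and with each tag tested on its own. These zeros show no stability, since in the setting of the simulation strains with true differences were not called at this spread either. The counts became 49 and 14 in quiet strains, a restriction that kept 9 of 87 strains with 6 spots per tag and a mean at or under -1 and 14 of 18 at or over 1, 360 and 170 with the array as the block, and 1 and 2 with the tag set as the block. The consensus correlation was -0.289 within arrays and 0.180 within tag sets. The array block treats the repeat of a tag on both arrays as independent, which narrows its errors. Its negative correlation narrows the error of a mean as well, and these effects were not separated. Strains 2-fold positive on both arrays (38) numbered 61 with the first and 70 with the second tag set, 10 among quiet strains, 237 at 1.5-fold, 3 at 3-fold, and 82 to 85 on single arrays. Those 2-fold negative (195) numbered 4 among quiet strains, where the restriction itself removes most such strains, 530 at 1.5-fold, 54 at 3-fold, and 305 to 1006 on single arrays, where array 1 alone gave 1006. Other alternatives moved these counts by under 1.5 times. Pearson's r was 0.493 in the first tag set and 0.720 in quiet strains; Spearman's rho was 0.647 in the second set and 0.750 in quiet strains. Lists past the threshold numbered 1 without centring (checkpoint) and 2 after quantile normalization (checkpoint and neighbours of TUB1), and 0 otherwise. With the estimated correlation hardly any list could have passed.

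Medians of uncalled lists near 0 changed sign. Prefoldin was 0.20 in the first tag set, 0.13 in the second and 0.34 in the 4 quiet members. CCT was -0.0323 without centring, -0.0287 in the first set and -0.00149 in the second. Other kinetochore proteins were 0.00422 after quantile normalization, 0.0866 and 0.0382 in the first and second set, and 0.70 in the 3 quiet members. Motors were -0.0815 without centring, -0.0201 in the second set and -0.00328 without the second tags of chromosome I. DASH was -0.0451 in the second set, dynein 0.0101 in the first, the spindle pole body -0.00926 without centring, ribosomal proteins 0.0865 in the 9 quiet members, and SWR1 0.17 in the first set and 0.12 without the second tags of chromosome I. Among named strains TUB2 was -0.0773 without centring, -0.0150 after quantile normalization and -0.0561 in the first set, CMD1 0.0295 in the first set, and URA5 -0.00292 in the first set. For these sign changes the cause was not tested, and in quiet strains few members remained and strongly negative ones had mostly been removed. The TUB1 direction check gave no value under any alternative. Spot brightness over background was not used here. No paired analysis was possible because there is 1 group and the contrast lies within each array.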

Other observations

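The tests in this part were chosen after the results were seen; the microtubule lists were fixed earlier.

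Further strains near both ends, outside the lists fixed earlier, are given as values. RSC4 (1.36 ± 0.33) and RSC1 (1.16 ± 0.06), both subunits of the RSC complex, stood with RSC9 and RSC8 near the positive end. MEC3, a DNA damage checkpoint clamp gene, had 1.31 ± 0.19, HTB1, a histone H2B gene, had 1.29 ± 0.19, and CTK3, a subunit of a kinase of RNA polymerase II, had 1.35 ± 0.19. AKR1, a palmitoyl transferase gene, had 1.30 ± 0.11. At the negative end both tags of both arrays put HIP1, the histidine permease gene, at -2.69 ± 0.05, DIG2, a regulator of mating genes, at -2.36 ± 0.06, and BAT2, a branched-chain aminotransferase gene, at -2.23 ± 0.03. SPT6, a histone chaperone gene, had -1.56 ± 0.09, and the TFIID subunits TAF5 and TAF6 had -1.57 ± 0.04 and -1.06 ± 0.05. Values are log2 ratios ± SD over 2 arrays, and these strains were chosen after their values were seen.

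Whether members of the 13 microtubule and chromosome segregation lists were in excess among precisely measured positive strains stays open. Among the 553 strains with 6 quiet spots per tag, limma called 49 positive and 14 negative, with a smallest adjusted p of 0.0456. Few strongly negative strains were among the 553, so both counts describe this selection and not the directions over all strains. The lists contributed 27 of the 553, of which 6 were called positive (CIN4, NUM1, CHL4, CIN2, CTF19 and YKE2) and 0 negative, with a one-sided Fisher's exact p of 0.0248. CIN4, NUM1, CHL4 and YKE2 had prompted the test. Without these 4, 2 of the other 23 members were called positive (8.70%, against 8.17% of strains outside the lists, one-sided Fisher's exact p 0.578). Leaving out 4 of the 6 called members lowers this share by construction, so the result does not count against an excess. The p of 0.0248 includes the strains that prompted the test, so it is no independent evidence for an excess either.

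Whether RSC subunits as a group lay above other strains stays open. All 15 measured subunits had a median of 0.11 (-0.07 on array 1 and 0.21 on array 2) and a camera p of 0.153 (adjusted p 0.229 over the 3 lists chosen afterwards, and 0.786 with an estimated correlation). The 11 subunits other than RSC9, RSC8, RSC4 and RSC1 had a median of -0.22 and a camera p of 0.533, and NPL6 stood at -2.15 ± 0.32. Leaving out the 4 highest subunits lowers the median of the rest by construction, so this result does not count against the group. Tags of some subunits also disagreed. STH1 had 1.96 and 1.94 for the first tag and -3.06 and -0.28 for the second. RSC6 had -1.31 and -1.85 for the first and 1.33 and 2.26 for the second. For TFIID the 11 measured subunits had a median of -1.02 (-1.10 on array 1 and -0.55 on array 2), with 8 negative and 2 positive on both arrays (camera p 0.0282, adjusted p 0.0847, and 0.786 with an estimated correlation). Without TAF5 and TAF6, which had prompted the list, the other 9 had a median of -0.61 and a camera p of 0.189. Whether TFIID subunits as a group lay below other strains therefore stays open. The estimated correlation decides nothing for RSC or TFIID. The COPII list, prompted by SEC13 at 1.20 ± 0.15, had a median of 0.00 over 9 members and a camera adjusted p of 0.576.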
